A study of Mus musculus with 6 samples.

How the data were processed

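Expression was measured with one-colour CodeLink mouse whole genome arrays in 3T3-L1 cells, a mouse preadipocyte line that accumulates lipid and takes on adipocyte features when treated with an adipogenic mixture. Per the labels, biotin-labelled total RNA came from adipocytes taken 10 days after differentiation, from cells carrying only the Tet-off plasmid (3 arrays) or expressing uncoupling protein 1, UCP1 (3 arrays). Groups were read from the source field of the labels, because the digit that closes the titles of the UCP1 arrays can be read as a replicate number or as part of a protein name. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

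The deposited values are spot intensities on a linear scale, scaled by the authors so that the array medians lay between 1.04 and 1.05. Scanner software, background correction and the scaling step are not given in the sources used here. From the values, the scale was linear and each array was set close to a common median, and between 80 and 159 values per array lay at or below 0. A code of -9999 stood for no value at 116 to 125 probes per array and was treated as missing. Intensities are relative to the array median, so a change in the total amount of RNA cannot be read from them. No detection mark and no mark of control spots was used here.

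Intensities were transformed to log2, with values at or below 0 set to the smallest positive value of their array. A probe was tested when at least 2 arrays per group had a value, which left 36116 of 36227 probes. Of all probes, 21615 had 1 gene symbol, 681 had several and 13931 had none in the platform annotation. Probes with several symbols were named by none. Symbols were checked through gene identifiers against RefSeq names of GRCm38.p6, where 21487 matched and 0 changed. That assembly was used for names and for the order of neighbouring genes only, since the array's build is not given in the sources used here.

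The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, two-sided, and Benjamini-Hochberg adjustment over all tested probes with a threshold of 0.05. The number of arrays, 3 per group, limits the precision. For Ucp1 an exact permutation test was also run, which with 3 against 3 arrays cannot give a p below 0.1. The same functions were tested on simulated arrays of 36062 probes with the measured levels of this comparison. Their spreads were those estimated by eBayes with the intensity trend, so the simulation cannot check the trend itself. Of 100 probes changed by 0.5 on the log2 scale 8% were recovered, of 50 changed by 1 82% were recovered, and of 50 changed by 2 100% were recovered. All changed probes were at or above the median level, so these rates do not cover dimmer probes. The simulation gave 7 false calls among 106, gave 2 calls when nothing was changed, and called 0 of 100 unshifted gene lists. Its noise was drawn independently for each probe, so it does not show how often lists of correlated genes are called by chance. In the data the estimated inter-gene correlation of a list reached 0.46, in oxidative phosphorylation.

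The design, the 21 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover adipocyte identity, lipid and mitochondrial metabolism, glycolysis, stress responses, the cell cycle, the extracellular matrix, inflammation, interferon response and markers of other cell types. Of 610 list entries 544 were measured. Each gene was represented by its probe with the highest mean log2 value, over 17992 genes. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes, so its direction is relative to them. Camera with an estimated correlation and fry, which tests whether the genes of a list move, on balance, in 1 direction, were run beside it.

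Genes were named by this rule. Ucp1 came first, then in each direction the 12 genes with the largest fold change among called probes with 1 symbol, groups that did not overlap and a level in the higher group at or above the median probe, passing over unnamed transcripts. From each list came the 4 called members with the largest fold change, or the 2 with the smallest p where none was called. Pparg, Cebpa, Fabp4, Adipoq, Lep, Slc2a4, Fasn, Lpl, Lipe, Ppargc1a, Cpt1a, Cpt1b and Ldha were always named. Ucp2 was also on that list and was not analysed here. Any other gene in the text was chosen after its values were seen.

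The alternatives were an offset of 0.168 added before log2, quantile normalization, median centring, the brighter part of the probes (at or above the median level), probes with a value on all arrays, eBayes without the trend, robust eBayes, array weights, an ordinary two-sample test per probe, the replicate number as a block, each array left out in turn, a fold threshold of 1.5 and an adjusted p threshold of 0.1. For the lists, the mean over all probes of a gene was also used. Cyclic loess normalization, the brighter probes without a trend, and fits without repeated unnamed spots were added after seeing the data. These last are 1260 spots at 126 places of the layout that recur 10 times with no gene symbol at any repeat, where 0.12 such places would be met by chance. They were kept among the tested probes as the design was written, and 10 of them were called.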

Results

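The series asked how forced expression of UCP1, the mitochondrial carrier that lets protons return to the matrix without making ATP, alters gene expression in 3T3-L1 adipocytes. It held 6 arrays, 3 of adipocytes carrying only the Tet-off plasmid (control) and 3 of adipocytes expressing UCP1, all taken 10 days after differentiation. Over the 18032 brighter probes, log2 values correlated at r = 0.993 to 0.995 among control arrays, 0.985 to 0.992 among UCP1 arrays and 0.976 to 0.988 between groups. The first principal component held 53.0% of the variance and parted the groups. Array medians were alike, but the 99th percentile of intensity was lower on the UCP1 arrays, at 225, 223 and 185, than on the control arrays, at 279, 255 and 258.

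Ucp1 was higher on every UCP1 array. Its probe (feature 68016) read 0.222, 0.232 and 0.278 on the control arrays, above 15.6% to 22.6% of the probes of each array. On the UCP1 arrays it read 2.34, 2.02 and 1.54, above 57.6% to 63.9% of the probes. The rise was 3.00 ± 0.234 (SE) on the log2 scale (limma, adjusted p = 0.00013), and 2.36 with an offset of 0.168 added before log2. Its control readings, at log2 -2.17, -2.11 and -1.85, lay near the medians of dim unnamed spots on the same arrays, at -2.26, -2.38 and -2.35, so the size of the rise depends on how dim values are treated. The exact permutation test gave p = 0.1, the smallest possible with 3 against 3 arrays. The call was lost with limma without the intensity trend (adjusted p = 0.0855) and with an ordinary test per probe (adjusted p = 0.132).

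Beyond Ucp1, the genes that rose most included Cyp2e1, a cytochrome P450 that oxidises ethanol and other small molecules. Its intensity went from 2.37 ± 0.198 (SD, n = 3) to 11.6 ± 3.04 (SD, n = 3), 4.81-fold. Crk, an adaptor protein of tyrosine kinase signalling, rose 4.47-fold, from 2.20 ± 0.0222 to 9.83 ± 0.657. Crabp1, which binds retinoic acid, rose 4.31-fold, and Cyp4b1, another cytochrome P450, 3.64-fold. Cndp1, which cleaves carnosine, rose by 1.55 on the log2 scale, Klkb1, the plasma kallikrein precursor, by 1.53, and the ephrin receptor Epha7 by 1.53. Eepd1 (1.97, and 1.18 without control 2), the immunoglobulin heavy chain gene Ighm (1.89), the phosphatase and actin regulator Phactr2 (1.85) and Ott (1.57) also rose on the log2 scale. Ighm had 5 probes, of which 4 were higher. Its control readings, at log2 -2.48, -1.57 and -1.49, included 1 below the median of dim unnamed spots on its array (-2.26 on control 1), and its rise was 1.41 with the offset. Ott belongs to a family of near-identical copies that a probe need not tell apart. With the offset the rises of Ott, Klkb1 and Epha7 were 1.32, 1.21 and 1.23.

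The genes that fell most were led by Ghrh, the hormone that releases growth hormone, which went from 39.0 ± 7.87 (SD, n = 3) in controls to 3.33 ± 0.840 (SD, n = 3), an 11.8-fold difference. Slc4a4, a sodium bicarbonate cotransporter, fell by 3.20 on the log2 scale on the called probe, by 2.57 with the offset before log2, and was lower on all 3 of its probes. Its UCP1 readings, at log2 -1.84, -1.65 and -2.35, lay near the medians of dim unnamed spots on those arrays, at -2.37, -2.29 and -2.74. Smim41 fell by 2.76 on the log2 scale. Mb, the oxygen-binding protein myoglobin, was bright in controls at 53.6 ± 14.2 and fell 4.28-fold to 12.4 ± 2.16, with its other probe called in the same direction. Ibsp, a bone matrix sialoprotein, fell by 2.26, Tmem229b fell by 2.06 and the ubiquitin ligase Mid2 fell by 2.05. The matrix protein Tgfbi fell by 2.15 and the phosphatase Dusp28 fell by 2.04, and each fell by 1.61 with the offset. The UCP1 readings of Tgfbi, at log2 -2.42, -1.06 and -2.26, lay near those dim spots on UCP1 arrays 1 and 3, and those of Dusp28 were -0.75, -1.63 and -2.13. Egln1, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation, fell by 2.01, and fell by 1.39 without UCP1 1. Pkm, the pyruvate kinase of glycolysis, fell by 1.98 and Cyp2ab1 fell by 1.84.

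**Figure D1:**
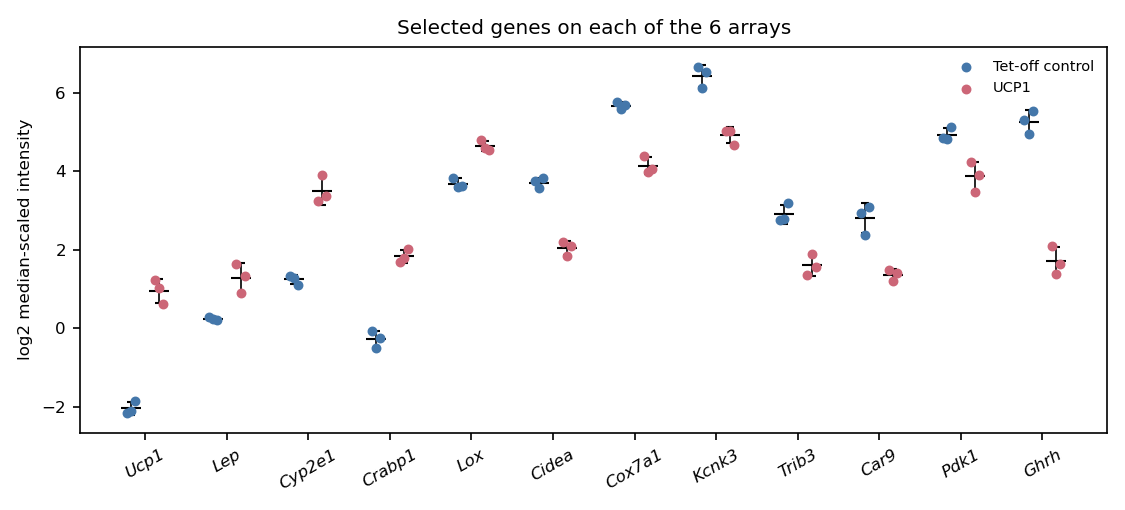
Log2 of the median-scaled intensity (vertical axis) of 12 selected genes on each array. Points are the 3 Tet-off control and 3 UCP1 arrays and black bars give the mean and SD; Ucp1 read 0.222 to 0.278 in controls and 1.54 to 2.34 in UCP1 before log2, and Ghrh differed 11.8-fold in the opposite direction.

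In all, 1021 of 36116 probes passed the threshold (limma, Benjamini-Hochberg), 289 higher and 732 lower in UCP1, covering 214 genes with a higher and 586 with a lower probe. In each of these 1021 probes the 3 UCP1 arrays lay wholly on 1 side of the 3 controls, which 21.9% of all tested probes did, against 10% by chance. Calls of at least 2-fold numbered 86 higher and 184 lower. The balance of directions depended on the scaling, since quantile normalization gave 567 higher and 446 lower calls and cyclic loess 517 higher and 460 lower, with 711 and 725 of the 1021 calls kept. No probe passed with limma without the intensity trend, where 4951 had an unadjusted p under 0.05, and 3 passed with an ordinary test per probe. Without the trend but on the brighter probes alone, a setting added after seeing the data, 2135 passed. These held all 927 of the 1021 calls that were tested there. The count was 359, 392 and 617 without control 1, 2 and 3, 1894 without UCP1 1, 1894 without UCP1 2 and 159 without UCP1 3.

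**Figure D2:**
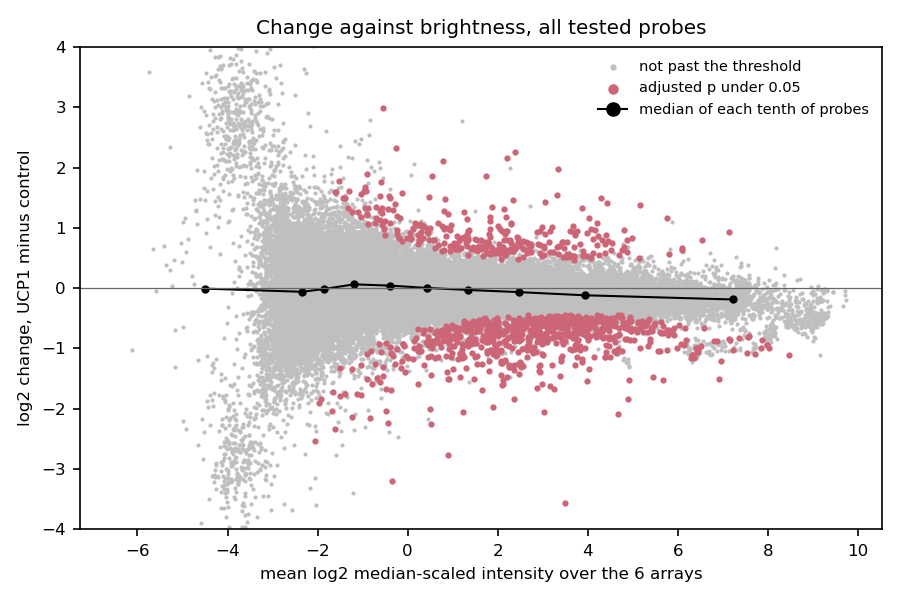
Log2 change, UCP1 minus control (vertical axis), against the mean log2 median-scaled intensity over the 6 arrays (horizontal axis) for tested probes; 33 probes beyond 4 on the log2 scale, none called, lie outside the plot. Red points are the 1021 called probes and the black line joins the medians of the 10 equal bins of brightness, which ran from 0.061 in bin 4 to -0.12 in bin 9 and -0.19 in bin 10, the brightest.

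Of 28 measured brown and beige adipocyte genes other than Ucp1, 6 fell, 9 adjusted over the list alone, and 0 rose, with 71.4% of members below 0. Cidea, a lipid droplet protein abundant in brown fat, fell 3.17-fold, Cox7a1, a cytochrome oxidase subunit of heart, muscle and brown fat, fell 2.89-fold, and Kcnk3, a potassium channel, fell 2.88-fold. The mitochondrial deacetylase Sirt3 fell by 1.16 on the log2 scale. The coactivator Ppargc1a was measured at -2.02 ± 0.599 (SE) and did not pass the threshold (limma, adjusted p = 0.0961), with -1.39 without control 1, -1.38 without UCP1 3 and -1.48 with the offset. Its reading on UCP1 3, at log2 -3.18, lay below the median of dim unnamed spots there (-2.74). Members that did not pass also included Cox8b, at -0.21, and Dio2, at 0.26. The list lay below other genes with a median of -0.37 (limma's camera, adjusted p = 0.00231), a call lost at adjusted p = 0.311 with an estimated correlation. That estimate, -0.0053, lay below the preset 0.01, so a higher correlation did not end the call. With fry the list passed (adjusted p = 0.00535). After quantile normalization its median was -0.23 and 5 members fell.

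Genes of mitochondrial energy production were mostly lower by small amounts. In oxidative phosphorylation, 2 of 50 members fell, 11 adjusted over the list alone, with 96.0% of members below 0 and a median of -0.39 on the log2 scale (camera, adjusted p = 6.42e-09, and adjusted p = 0.407 with an estimated correlation). After quantile normalization 32 of the 50 lay below 0, with a median of -0.09, 0 calls and camera's adjusted p = 0.0472. The 2 were Atp5b, a subunit of ATP synthase, which fell by 0.95, and Sdhd, a membrane anchor of complex II, which fell by 0.68. Of 40 genes of mitochondrial biogenesis, import and chaperones 5 fell, 13 adjusted over the list alone. They included the chaperone Dnaja3, which fell by 0.86, and the import receptor Tomm22 and the import channel Tomm40, which both fell by 0.59. Phb, a scaffold of the inner membrane, fell by 0.57 on its brighter probe, while its other probe went the opposite way. The list's median was -0.30 (camera, adjusted p = 6.85e-08, and adjusted p = 0.311 with an estimated correlation), and after quantile normalization it was -0.11 with 0 calls. In the tricarboxylic acid cycle list, 0 of 22 members passed over all probes and 13 fell adjusted over the list alone, among which Fh1, at -0.48, and Suclg1, at -0.65, had the smallest p and Got1, at -0.94, the largest change (camera, adjusted p = 1.76e-05, and adjusted p = 0.311 with an estimated correlation). The list's median went from -0.39 to -0.18 after quantile normalization, where 1 member rose and 0 fell. In fatty acid oxidation, Crat, the carnitine acetyltransferase, was the 1 of 25 members that fell (11 adjusted over the list alone), by 0.66 (limma). Cpt1a, which admits fatty acids to mitochondria, was measured at 0.02 ± 0.224 (SE) and Cpt1b at -0.21 ± 0.660 (SE). The oxidation list's median was -0.40 (camera, adjusted p = 0.000874), with adjusted p = 0.311 with an estimated correlation, and -0.16 with 0 calls after quantile normalization (adjusted p = 0.0548).

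In the deposited scaling, the lowest list medians were those of glycolytic and hypoxia-responsive genes. After quantile normalization the hypoxia list, at -0.53, stayed lowest, and the integrated stress response list, at -0.36, lay below glycolysis, at -0.32. Of 21 genes of glucose uptake, glycolysis and lactate 6 fell, 15 adjusted over the list alone, with a median of -0.61 (camera, adjusted p = 1.92e-07, and adjusted p = 0.311 with an estimated correlation). Besides Pkm, the triose phosphate isomerase Tpi1 fell 2.54-fold, Pdk1, the kinase that restrains pyruvate dehydrogenase, fell 2.10-fold and the phosphofructokinase Pfkl fell 2.06-fold. Slc2a4, the insulin-responsive glucose transporter, fell 1.67-fold, and Ldha, which makes lactate, was measured at -0.68 ± 0.222 (SE) without passing (limma, adjusted p = 0.13). Tpi1 and Slc2a4, like Klkb1 and Tomm22 above, each had 2 probes in the same direction, of which 1 was called. In the hypoxia response list, 7 of 18 members fell (4 after quantile normalization) and 1 rose, against 11 and 1 adjusted over the list alone, with a median of -0.61 (camera, adjusted p = 2.79e-05, and adjusted p = 0.311 with an estimated correlation). With Egln1 these included Car9, a carbonic anhydrase, which fell 2.72-fold, the transcription factor Bhlhe40, which fell 2.70-fold, and Ddit4, an inhibitor of mTORC1 signalling, which fell 2.10-fold. The member that rose was Lox, a collagen cross-linking enzyme.

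The integrated stress response list had no member above 0 in the deposited scaling, and 23 of 26 below 0 after quantile normalization. Of 26 genes 8 fell (5 after quantile normalization), 17 adjusted over the list alone, with a median of -0.53 (camera, adjusted p = 5e-09, and adjusted p = 0.311 with an estimated correlation). Slc7a5 and Slc3a2, which together form an amino acid exchanger, fell 2.52-fold and 2.21-fold, Trib3, a pseudokinase induced by ATF4, fell 2.47-fold and Chac1, which degrades glutathione, fell 2.27-fold. In the oxidative stress list, 4 of 28 fell and 0 rose, against 7 and 1 adjusted over the list alone. The mitochondrial thioredoxin reductase Txnrd2 fell by 0.75, its partner Txn2 fell by 0.74, Srxn1, which repairs peroxiredoxins, fell by 0.56 and the mitochondrial superoxide dismutase Sod2 fell by 0.56. That list's median was -0.29 (camera, adjusted p = 0.00256), with adjusted p = 0.431 with an estimated correlation. After quantile normalization it was -0.08, with 2 members that fell and 1 that rose (camera, adjusted p = 0.172).

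Adipocyte identity genes went in both directions. Of 26 members 2 rose and 3 fell, against 2 and 4 adjusted over the list alone. The hormone gene Lep rose 2.05-fold and the lipocalin Apod 1.96-fold, while Bscl2, the seipin that shapes lipid droplets, fell 2.44-fold, the transcription factor Cebpd fell 2.02-fold and Slc2a4 fell as given above. Pparg, the main regulator of adipocyte differentiation, was measured at -0.21 ± 0.155 (SE), the fatty acid binding protein Fabp4 at -0.07 ± 0.258 (SE), Adipoq at -0.12 ± 0.244 (SE), Lpl at -0.05 ± 0.248 (SE) and Cebpa at -0.69 ± 0.248 (SE), none past the threshold, and all but Cebpa turned positive under quantile normalization. Fabp4, Adipoq and Lpl averaged 722, 880 and 853 in controls and 693, 818 and 831 in UCP1. Array maxima were 932 to 943 in controls and 683 to 950 in UCP1, so changes near the top of the scale may be hidden. The list's median of -0.15 did not pass (camera, adjusted p = 0.168), and its direction turned under cyclic loess (adjusted p = 0.828).

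Lipid synthesis genes were lower relative to other genes. In fatty acid and triglyceride synthesis, 4 of 24 members fell and 1 rose, against 7 and 1 adjusted over the list alone, with a median of -0.35 (camera, adjusted p = 0.00132, and adjusted p = 0.413 with an estimated correlation). After quantile normalization 2 fell and 2 rose, with a median of -0.12 (camera, adjusted p = 0.0472). The stearoyl desaturase Scd2 fell 1.84-fold, Slc25a1, which exports citrate from mitochondria, fell 1.72-fold and the acyltransferase Mogat1 fell 1.64-fold, while the elongase Elovl6 rose 1.48-fold. Fasn, the fatty acid synthase, was measured at -0.27 ± 0.159 (SE). In lipolysis and the lipid droplet, Cidea and the phosphodiesterase Pde3b, which fell by 0.66, were the 2 of 19 that fell, 3 adjusted over the list alone. The hormone-sensitive lipase Lipe was measured at 0.30 ± 0.640 (SE). The lipolysis list passed at camera's adjusted p = 0.0398 but not with an estimated correlation (adjusted p = 0.471), after quantile normalization (adjusted p = 0.672) or without control 1 (0.0769), control 2 (0.0756) or UCP1 3 (0.179). In cholesterol synthesis 0 of 17 passed and 6 fell adjusted over the list alone, among which Sqle, at -1.03, and Msmo1, at -0.45, both sterol-forming oxygenases, had the smallest p (camera, adjusted p = 0.00256, and adjusted p = 0.426 with an estimated correlation). The list's median went from -0.30 to -0.15 after quantile normalization.

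Extracellular matrix and inflammatory genes were higher relative to other genes. Of 42 preadipocyte, fibroblast and matrix genes 6 rose and 1 fell, against 8 and 2 adjusted over the list alone, with a median of 0.10 (camera, adjusted p = 0.00256, and adjusted p = 0.455 with an estimated correlation). After quantile normalization 12 rose and 1 fell, with a median of 0.29. Lox rose 1.96-fold, Lum, a small collagen-binding proteoglycan, 1.87-fold and the surface marker Thy1 1.74-fold, whereas Acta2, the smooth muscle actin, fell 2.61-fold. Of 27 genes of inflammation and the acute phase 4 rose and 0 fell, against 9 and 2 adjusted over the list alone, with a median of 0.11 (camera, adjusted p = 0.00231, and adjusted p = 0.311 with an estimated correlation), against 6 and 0 with a median of 0.19 after quantile normalization. The chemokines Cxcl5 and Ccl7 rose 2.52-fold and 1.69-fold, the pentraxin Ptx3 1.83-fold and the acute phase protein Orm2 1.71-fold. Cxcl5 was dim in controls, at log2 -1.32, -1.22 and -1.19. Its rise went from 1.33 to 1.06 on the log2 scale with the offset. None of 28 interferon response genes passed over all probes or adjusted over the list alone, with Oas2 at 0.83 and Oasl2 at 0.60 (camera, adjusted p = 0.0662). Of 34 cell cycle genes 0 rose and 1 fell, against 0 and 2 adjusted over the list alone. That gene was Cdkn1a, an inhibitor of cyclin-dependent kinases, which fell 2.42-fold. The cell cycle list did not pass (camera, adjusted p = 0.703), and its median of -0.07 and its test differed in sign.

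Markers of other cell types did not move as groups at the preset threshold. Of 15 macrophage genes Lyz2, a lysozyme, rose 2.80-fold and 0 fell, the same counts adjusted over the list alone (camera, adjusted p = 0.15), and the list's median of -0.01 and mean of 0.05 differed in sign. Of 20 skeletal muscle genes Actn3 rose 2.04-fold and Mb fell, 1 and 2 adjusted over the list alone (camera, adjusted p = 0.838), where the median of -0.09 and the test differed in sign. Of 16 bone and cartilage genes 4 fell, Ibsp, Col11a1, Alpl and Comp, and 5 adjusted over the list alone. Col11a1, a fibrillar collagen, fell by 0.99, the phosphatase Alpl fell by 0.98 and the cartilage matrix protein Comp fell by 0.81. Comp had 2 probes in the same direction, of which 1 was called. That list missed the threshold (camera, adjusted p = 0.0529) and passed after quantile normalization (adjusted p = 0.0214). None of 18 epithelial and endothelial genes passed over all probes or adjusted over the list alone, with Krt5 at 0.44 and Cldn4 at -0.72, and their median of 0.21 and mean of -0.04 differed in sign (camera, adjusted p = 0.173).

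**Figure D3:**
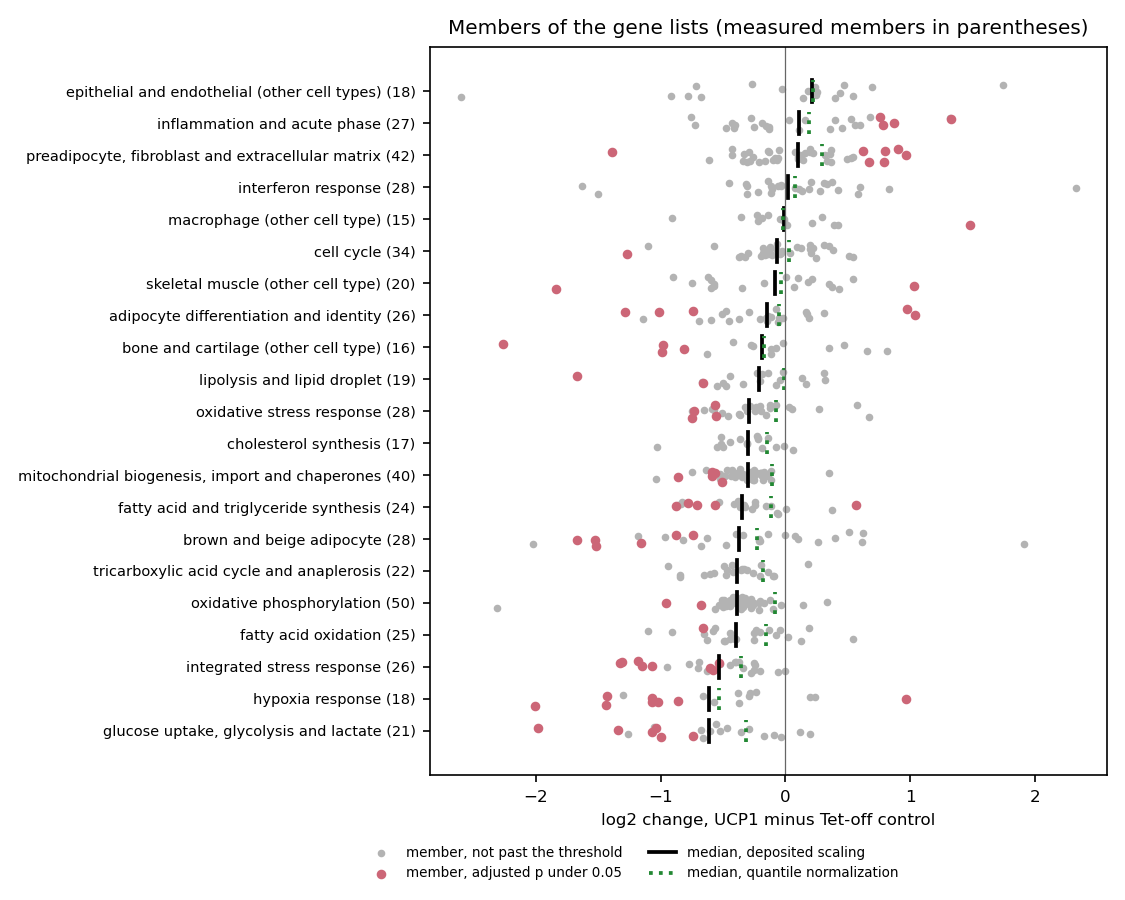
Log2 change, UCP1 minus Tet-off control (horizontal axis), of the measured members of the 21 gene lists (vertical axis, number of members in parentheses). Red points passed the threshold over all probes, black bars are list medians in the deposited scaling and green dotted bars those after quantile normalization; the medians of the glycolysis and hypoxia lists, both -0.61, moved to -0.32 and -0.53.

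Across the 21 lists, 14 passed with limma's camera at the preset correlation, 12 lower and 2 higher, 0 passed with an estimated correlation and 9 passed with fry. Of 73 called probes of named genes besides Ucp1, 15 lost the call after quantile normalization, those of Atp5b, Cdkn1a, Crat, Dnaja3, Eepd1, Egln1, Phb, Scd2, Sdhd, Slc3a2, Slc7a5, Sod2, Tomm22, Tomm40 and Txn2, and 43 lost it without UCP1 3.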

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

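Cyclic loess, the brighter probes without a trend, and the fits without repeated unnamed spots were chosen after seeing the data, and the cause of a change was not tested except where fewer probes or arrays were used by construction. All 1021 calls that were tested kept their direction in every setting. Their groups did not overlap, so only median centring, quantile normalization and cyclic loess could have turned a call. Against 1021 probes (289 higher, 732 lower), adjusted p under 0.1 gave 2175 (566, 1609), the brighter probes 2239 (523, 1716), the brighter probes without a trend 2135 (490, 1645), array weights 2206 (491, 1715), the ordinary two-sample test 3 (1, 2) and no intensity trend 0 (0, 0) with 4951 at an unadjusted p under 0.05. Quantile normalization gave 1013 (567, 446), cyclic loess 977 (517, 460) and quantile normalization without repeated unnamed spots 1163 (621, 542), so that calls higher in UCP1 went from 28.3% to 56.0%, 52.9% and 53.4%. Leaving out 1 array gave 159 (without UCP1 3) to 1894 (without UCP1 1 or UCP1 2) probes, 66 to 395 higher and 93 to 1610 lower. The other settings stayed within 1.5 times, and leaving out the repeated unnamed spots gave 1063 (298, 765). Ucp1 stayed 3.00 higher on the log2 scale without the trend (adjusted p = 0.0855) and with the ordinary test (adjusted p = 0.132), where its call ended, and ran from 2.86 to 3.16 with 1 array left out, always called by limma. With the offset it was 2.36.

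Same-numbered arrays did not deviate together over the brighter probes, with correlations of -0.24, -0.0069 and 0.10 for numbers 1, 2 and 3. The labels name no batch, and a weak shared effect would not show in these values, so pairing by number is not excluded. With the replicate number as a block in limma, 776 probes passed (225 higher, 551 lower), of which 727 were among the 1021.

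Of the 14 lists called by limma's camera, 0 held with an estimated correlation. For the brown list that estimate, -0.0053, lay below the preset 0.01, so a higher correlation did not end its call. Adjusted p was then 0.311 for fatty acid oxidation, the tricarboxylic acid cycle, glycolysis, brown adipocyte, mitochondrial biogenesis, integrated stress, hypoxia and inflammation. It was 0.407 for oxidative phosphorylation, 0.413 for fatty acid synthesis, 0.426 for cholesterol, 0.431 for oxidative stress, 0.455 for matrix and 0.471 for lipolysis. With fry 9 lists passed, bone and cartilage newly at adjusted p = 0.026, while fatty acid synthesis (0.0599), lipolysis (0.122), oxidative stress (0.0563), cholesterol (0.131), matrix (0.528) and inflammation (0.13) did not. Fry turned the uncalled cell cycle (0.218) and muscle (0.632) lists, the mean over probes turned cell cycle (0.914) and the ordinary test did so too (0.941).

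Lipolysis also lost its call with quantile normalization (adjusted p = 0.672), cyclic loess (0.609), quantile normalization without repeated unnamed spots (0.496), the brighter probes with (0.144) and without (0.14) the trend, no trend (0.0836) and the ordinary test (0.112), and ranged from 0.00751 to 0.179 with 1 array left out. Oxidative stress lost it with quantile normalization (0.172), cyclic loess (0.0966) and quantile normalization without repeated unnamed spots (0.0572), and fatty acid oxidation with quantile normalization (0.0548). Bone and cartilage gained a call with the offset (0.0493), quantile normalization (0.0214), cyclic loess (0.0185), robust eBayes (0.0389), the brighter probes with (0.00337) and without (0.00283) the trend and quantile normalization without repeated unnamed spots (0.0198), and ranged from 0.0253 to 0.2 with 1 array left out. Interferon response gained one with the mean over probes (0.0433), the brighter probes with (0.0195) and without (0.0202) the trend and array weights (0.00906), and ranged from 0.00059 to 0.799 with 1 array left out. Macrophage gained one on the brighter probes with (0.0313) and without (0.0282) the trend. The uncalled muscle list turned with quantile normalization (0.631), cyclic loess (0.658) and quantile normalization without repeated unnamed spots (0.664) and ranged from 0.49 to 0.918 with 1 array left out. Cell cycle ranged from 0.388 to 0.928, and adipocyte identity turned with cyclic loess (0.828).

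No called named gene turned direction, which only median centring, quantile normalization or cyclic loess could have brought about. Of 92 named probes besides Ucp1 73 were called, and 58 of these stayed called with the offset, median centring, quantile normalization and cyclic loess. Among the 7 uncalled ones that turned, quantile normalization gave log2 changes of 0.0584 for Pparg, 0.237 for Fabp4, 0.0433 for Adipoq and 0.0887 for Lpl. Cyclic loess gave 0.0348 for Pparg, 0.249 for Fabp4, 0.216 for Adipoq, 0.279 for Lpl and -0.00181 for Cpt1a. Quantile normalization without repeated unnamed spots gave 0.148 for Fabp4, 0.0433 for Adipoq and 0.0887 for Lpl. With 1 array left out, Adipoq ranged from -0.206 to 0.0135, Cpt1a from -0.171 to 0.173, Cpt1b from -0.686 to 0.418, Fabp4 from -0.213 to 0.118, Lipe from -0.0183 to 0.546 and Lpl from -0.156 to 0.0963. In the 2 dimmest of 10 brightness bins no probe was called, and Lipe and Cpt1b, at 0.151 and 0.202 in controls, lay far below the array median.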

Other observations

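The gene families, the comparison of the directions of calls, the splits of the arrays, the brightness test of the listed genes, the comparison of the whole brown list with adipocyte genes and the comparisons that keep the brightest adipocyte genes were chosen only after the result was seen.

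Gene families defined by symbol, 13 in all, were also examined, and some share members with the fixed lists, such as Slc25a1 and Col11a1. Of 72 mitochondrial ribosomal protein genes 66 lay below 0, 6 fell and 0 rose, with a median of -0.26 (limma's camera, adjusted p = 3.63e-07, and adjusted p = 0.49 with an estimated correlation). Mrpl45 fell by 1.36 and Mrps11 fell by 0.79, and after quantile normalization the median was -0.08 (camera, adjusted p = 0.0223). Of 48 translation initiation factors and their binding proteins 3 fell, Eif5a, Eif4e3 and Eif4ebp2, with a median of -0.27 (camera, adjusted p = 0.000153, with an estimated correlation adjusted p = 0.49, after quantile normalization 0.0916). Cytosolic ribosomal proteins, among the brightest genes, had a median of -0.21 that turned to 0.14 after quantile normalization, so their direction rests on the scaling. Proteasome subunits had a median of -0.19 and mitochondrial solute carriers one of -0.26, which were -0.01 and -0.13 after quantile normalization. Of 500 olfactory receptor genes, which are dim here, 1 rose, and the median was 0.07 (camera, adjusted p = 0.000153, with an estimated correlation adjusted p = 0.301, after quantile normalization 0.105).

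Spots that recur over the array with no gene symbol gave a view of the arrays apart from named genes. The 640 in the outermost columns had median log2 values of 7.48, 7.38 and 7.42 on the control arrays and 7.41, 7.40 and 6.92 on UCP1 arrays 1, 2 and 3. The 283 bright inner ones had medians of 8.72, 8.52 and 8.23 on the control arrays and 7.42, 8.16 and 7.61 on the UCP1 arrays. The 337 dim ones had array medians between -2.26 and -2.74. Their content is not given in the sources used here.

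More probes were called lower than higher in UCP1. No single array turned this, since the share of calls higher in UCP1 stayed at or below 44.3% whichever array was left out (the highest value, without control 1). The excess narrowed to 200 lower against 159 higher without control 1 and 93 against 66 without UCP1 3, so 1 array may account for part of it. The deposited scaling may account for it, since brighter probes were lower on the UCP1 arrays and the share of higher calls went from 28.3% to 56.0% after quantile normalization, although a real loss of abundant transcripts would look the same. The real split of the 6 arrays gave 1021 calls and was 1 of 10 splits to reach that number, with 0 calls as the highest of the others, and 10 splits are too few for a share under 0.05.

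Genes of the hypoxia, glycolysis and integrated stress response lists were lower together, 57 of 61 pooled genes with a median of -0.55, and 20 of 28 brown adipocyte genes were lower with a median of -0.37. The pooled median lay at percentile 0 of 10000 random lists matched on level. That percentile makes no allowance for the inter-gene correlations of the 3 lists, estimated at 0.18 to 0.19, so it does not show how often correlated lists fall this far. The lowest median of the 10 brightness bins was -0.19. After quantile normalization the medians of the hypoxia, glycolysis and stress response lists were -0.53, -0.32 and -0.36. These values argue against brightness alone as the source of the shift. No single UCP1 array carried the shift, since the pooled genes' lowest control array median lay 0.32 above their highest UCP1 array median. The 3 lists had the lowest medians of the 21 in these same data, which favours each of these results. A smaller share of adipocytes on the UCP1 arrays cannot be told apart from the shift of the 3 lists, because 20 adipocyte identity genes, taken without the brightest 1% of genes, lay 0.31 ± 0.16 (bootstrap SE) above it, less than the difference of 2 SE set for excluding it, and the bar was met only with the brightest kept (25 genes, 0.41 ± 0.11). Nor can it be told apart for the brown list, since 21 adipocyte genes taken the same way, with a median of -0.29 ± 0.15 (bootstrap SE), lay 0.076 ± 0.24 above it, and all 26, with a median of -0.15, lay 0.21 ± 0.22 above it. The brightest adipocyte genes that the fuller sets keep, such as Adipoq and Lpl, lay near the array maxima, where a fall may be hidden. Of 42 preadipocyte, fibroblast and matrix genes 6 rose, among them Pdgfra at 0.67, Dcn at 0.79, Thy1 at 0.80 and Lum at 0.90. The 1 that fell was Acta2, at -1.39 (12 rose and 1 fell after quantile normalization), and 45.2% of members lay below 0. After quantile normalization 14 members lay below 0. More of the called markers thus rose than fell, and a smaller share of adipocytes stays open. So do an effect of UCP1 itself and a separate history of the UCP1-expressing cells, which were not tested.

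Neighbouring genes also shifted together, most in a run of 40 from Rps6ka6 to Prps1 in the gene order of GRCm38.p6. Only 10744 genes, all at or above the median probe level, were ordered, so dimmer genes lying between them were passed over. After the median change at each level of brightness was removed, 30 of these genes were higher and 10 lower, and 5 of the 40 were called. The running median over these and the next gene, 0.26, was the largest of 9961 windows. It lay above the 95th percentile (0.21) of 1000 shuffled orders, of which 0.4% had one as large. In all 20 windows, which can overlap, lay beyond that percentile, and only the largest was located. A chromosome segment gained in the UCP1-expressing cells, or lost in the control cells, is a candidate explanation that fits this value. Shared regulation of neighbouring genes was not tested. Crk rose without a called gene among the 5 measured on each side, the highest of which, Slc43a2, was at 0.38 (limma, adjusted p = 0.0827). Several of these neighbours were dim, such as Doc2b, with a mean log2 level of -2.38 and an SE of 0.63. Such genes could hardly have been called, so a shift around Crk is not excluded.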
